A study of Mus musculus with 8 samples.

How the data were processed

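Poly(A)-selected RNA of BV2 cells was sequenced from libraries made with a directional kit, per the labels' protocols. The deposited tables hold, for each of 8 libraries, read counts per gene, which the authors left as whole numbers, and TPM values, which the authors scaled to 1000000 per library once repeated symbols are taken once. FastQC, Trimmomatic, STAR, featureCounts and DESeq2 are named, without versions or roles, per the submitters' processing notes. The strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. The submitters' processing notes name GRCm38, but only 1423 of 51991 nuclear genes (2.74%) in the deposited table start where the GRCm38 annotation places them, so coordinates are given as the table has them with no build.

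Each table had 57010 rows. A total of 148 symbols stood on several rows with identical counts, and 151 repeated rows were dropped, leaving 56859 genes. No row lacked a gene name. The libraries were mapped to groups by their titles. Total counts were 21582156 in the control and 18056693 in the 10panx1 library at 6 h, 21201692, 21247934 and 19146009 in the controls at 9 h, and 21551229, 21317713 and 23164860 in the 10panx1 libraries at 9 h. Replicate pairs at 9 h differed by more than sampling noise, with a chi-square per degree of freedom from 4.03 to 7.04, so none was counted as a duplicate.

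The deposited counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) using TMM scaling, filterByExpr, a quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. The comparison at 9 h used its 6 libraries with no block. The comparison of 9 h against 6 h used all 8 libraries with treatment as a covariate, and the interaction was tested in the same libraries. Standard errors were taken from the quasi-likelihood statistic. Levels are TMM-scaled CPM, and log2 ratios at 6 h used a prior count of 2. No test was made between the single libraries at 6 h.

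The 36 gene lists, the main tests of genes and lists and the rule for named genes were chosen before the data were examined. Settings added later are named below, and what would count for or against a shift along the time course and reads of another organism was written after their values were seen. Of 802 list entries 782 matched by symbol, 1 by synonym, 18 by Ensembl ID and 1 not at all. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. The rule named Panx1 and Src and, at 9 h, the 6 largest rises and falls among called genes with no overlap between groups. These had a mean of at least 50 counts and a symbol other than a Gm number, Rik clone, pseudogene, RP clone or accession. Larger changes in excluded genes may thus be unnamed. It also named up to 3 members with the smallest p from each called list, or up to 2 from other lists with at least 3 called members. For 9 h against 6 h it named the 5 largest rises and falls under the same symbol, call and count criteria. For these both libraries at 6 h lay on the same side of all libraries at 9 h. Up to 2 members from each called list were also named. Chance alone leaves 10% of genes without overlap between 3 and 3 libraries.

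The scripts were tested on simulated counts, in a single run per comparison, with 200 changed genes, each with a mean of at least 50 counts. All 1.25-fold and 1.5-fold changes were rises, and all 2-fold and 4-fold changes were falls. Recovery of small falls, large rises and changes in genes with lower counts was not simulated. At 9 h, over 13198 genes, the test recovered 56% of 1.25-fold, 86% of 1.5-fold and 100% of 2-fold changes. In that run 9.04% of its calls (17 genes) were false, above the nominal rate, though a single run does not measure a rate. For 9 h against 6 h, over 13885 genes, it recovered 62%, 94% and 96%, with 8.81% of calls false. For the interaction, over 14621 genes, it recovered 2%, 42% and 66%.

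Alternatives were other scalings (RLE, upper quartile), other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) of genes with a mean TPM of at least 1, fits on all 8 libraries, a replicate block, and leaving out each library. Removal of each library's trend with transcript length and GC, for the 98.7% of tested genes with both values, was added after the data were seen. Marker lists of 8 other cell types or tissues were also added then, as were interaction fits with no filter and each 9 h library left out in turn. Summaries and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.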

Results

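RNA from BV2 cells, an immortalized mouse microglial line, was sequenced after oxygen-glucose deprivation with or without 10panx1, a peptide that blocks channels of pannexin 1 (Panx1). The 8 libraries fell into 4 groups by their titles. There were 3 control and 3 10panx1 libraries at 9 h, and 1 control and 1 10panx1 library at 6 h. The title of the 10panx1 library at 6 h names the peptide while its treatment label does not, and it was grouped by title. The labels do not say what the 6 h and 9 h count, and they describe 9 h of deprivation followed by recovery. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Total counts per library ran from 18056693 to 23164860, so that 3 counts corresponded to between 0.13 and 0.166 counts per 1000000 counts (CPM). Mitochondrial transcripts took from 1.141% to 1.515% of the counts. The third control library at 9 h stood apart. In it 82 genes had at least 20 counts and over 10 times the count of any other library, among them Hpx, Fgb and Col1a1, against at most 1 such gene in each other library. These genes held 0.0736% of its counts, and 1 of them, Serpinc1, named here after its value was seen, was called in the comparison at 9 h.

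The first comparison, deprivation with 10panx1 against deprivation alone at 9 h, addresses which transcripts accompany an increase in Src with 10panx1. The titles name no control peptide, so a block of Panx1 channels cannot be told apart from other effects of the peptide. Src, a non-receptor tyrosine kinase, rose from 61.2 ± 6.38 CPM (SD, n = 3) in control libraries to 84.7 ± 9.06 CPM (n = 3) with 10panx1, a log2 fold change of 0.47 with a standard error of 0.083 (edgeR, adjusted p = 0.0035). Panx1 itself lay at 32.1 ± 1.77 CPM in control and 31.7 ± 3.85 CPM in 10panx1 libraries, with a log2 fold change of -0.02 and a 95% interval from -0.21 to 0.17 (edgeR, adjusted p = 0.922). In the coordinates of the deposited table, whose build is not named in the table, Src (ENSMUSG00000027646) spans chromosome 2 from 157260364 to 157313782 on the plus strand and Panx1 (ENSMUSG00000031934) spans chromosome 9 from 14913424 to 14956774 on the minus strand. Src was higher in each 10panx1 library than in each control library. With limma on log2(TPM + 1) the estimate for Src was 0.46 with an adjusted p of 0.0515, the highest over 18 alternatives. The lowest adjusted p was 1.12e-11, in the edgeR fit without a filter alone, and the next lowest was 1.46e-05 with DESeq2.

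Among genes named by the fixed rule, Slc6a19, a neutral amino acid transporter, rose from 2.7 ± 0.252 to 5.63 ± 1.31 CPM, and Serpinb2, a plasminogen activator inhibitor, rose from 10.6 ± 2.42 to 21.1 ± 3.99 CPM. Dhrs3, a retinal reductase, rose from 13.03 ± 1.88 to 24.96 ± 3.96 CPM. Celsr3, Ksr2 and Trim10 rose by 1.02, 1.01 and 1.00 on the log2 scale. Hspa2, a heat shock protein 70 family member, fell from 3.98 ± 1.13 to 1.57 ± 0.286 CPM, and Ccno and Trim36 had log2 fold changes of -1.23 and -1.11. Arc, an activity-regulated gene, fell from 17.6 ± 1.02 to 8.27 ± 1.48 CPM. Irf1, a transcription factor of the interferon response, fell from 8.09 ± 0.352 to 3.87 ± 0.554 CPM, and Arl4d had a log2 fold change of -1.06. In all, 1233 of 13392 tested genes (9.21%) were called, 678 higher and 555 lower with 10panx1, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts of called list members below are to be read against this share. The median size of the called changes was 1.249-fold, 188 reached 1.5-fold and 45 reached 2-fold. The count fell to 598 without control replicate 1, 695 without control replicate 2, 676 without 10panx1 replicate 2 and 600 without 10panx1 replicate 3. Tests on the deposited TPM called 368 genes. Of the 64 called genes named at 9 h, here and below, 34 kept the call in each alternative and 42 in each fit without 1 library.

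**Figure D1:**
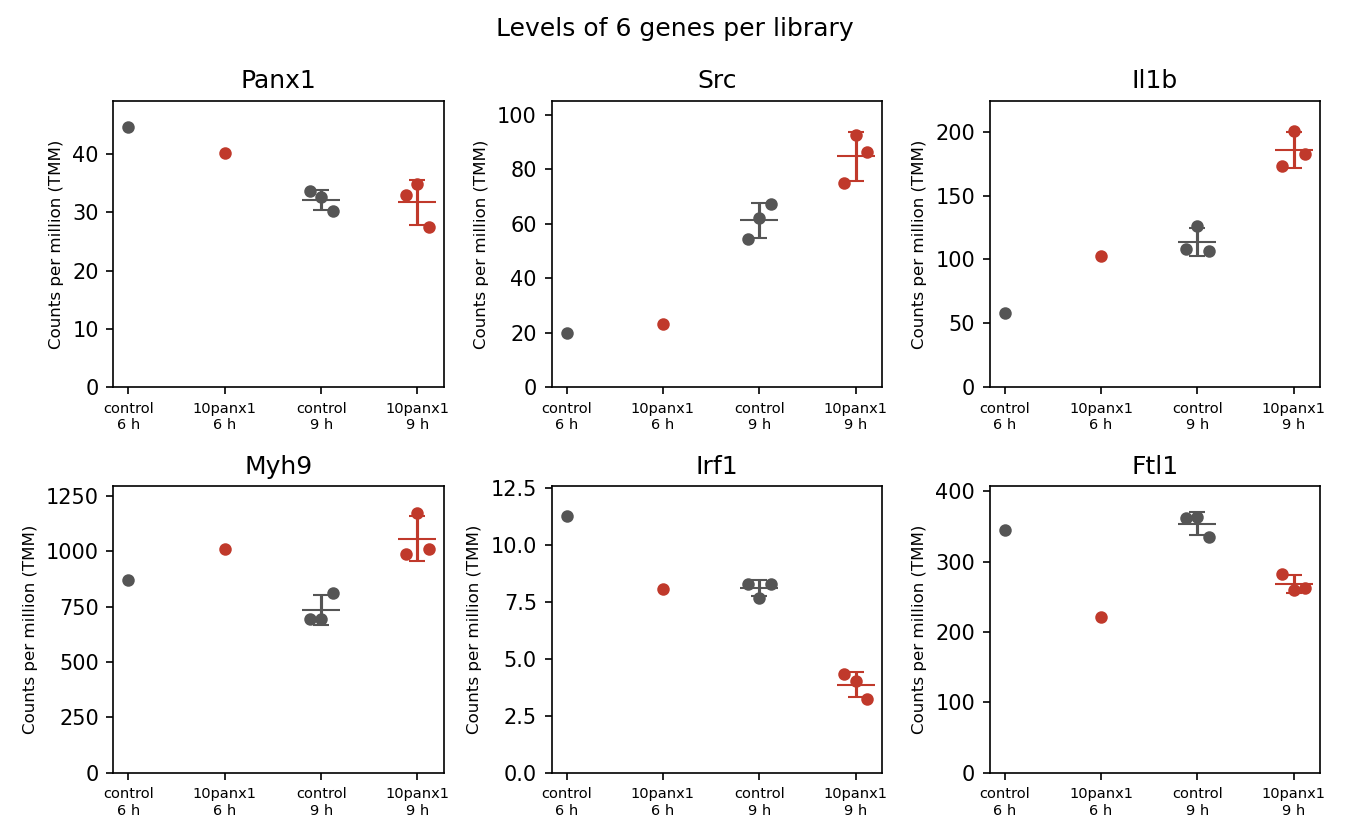
Levels in CPM (TMM-scaled, linear axis from 0) of 6 genes in each of the 8 libraries by group, with points for libraries and, at 9 h, a bar at the mean and whiskers of 1 SD (n = 3). The Src values at 9 h were 61.2 ± 6.38 in control and 84.7 ± 9.06 with 10panx1, while the groups overlapped for Panx1.

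Proinflammatory cytokines and chemokines rose as a list. Of 22 tested members 9 rose and none fell, and 12 rose and 1 fell when adjusted over the list alone. Il1b rose from 114 ± 10.95 to 186 ± 13.9 CPM, Il6 from 15.2 ± 1.03 to 25.5 ± 1.95 CPM and Tnf from 214 ± 8.71 to 262 ± 4.65 CPM. The list passed the camera test of edgeR and limma with a preset correlation (adjusted p = 1.27e-09), and had an adjusted p = 0.332 with an estimated correlation. Of 20 NF-kB feedback genes, which restrain or relay signalling by that transcription factor, 8 rose and 1 fell, and 8 rose and 3 fell adjusted over the list alone. Tnip1, Tnfaip3 and Nfkb1 each rose by 0.22 on the log2 scale. The camera call of this list (adjusted p = 0.0249) had an adjusted p = 0.477 with an estimated correlation, and was lost by ranks (adjusted p = 0.0887), without control replicate 3, the library that stood apart (adjusted p = 0.178), and without 10panx1 replicate 2 (adjusted p = 0.0667). Among genes of alternative activation 3 of 15 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone. Il1rn, the interleukin 1 receptor antagonist, rose from 986 ± 116 to 1414 ± 196 CPM, Stab1 rose by 0.38 on the log2 scale and Klf4 fell from 26.2 ± 4.7 to 19.4 ± 2.15 CPM. The list's adjusted p by camera was 0.00704, with an adjusted p = 0.193 with an estimated correlation. Of 32 interferon-stimulated genes 3 rose and 1 fell, near the share called over all tested genes. The counts were the same adjusted over the list alone. Oasl1 rose from 109 ± 7.5 to 139 ± 9.6 CPM and Isg20 rose by 0.38 on the log2 scale, whereas Stat2 fell from 23.5 ± 1.45 to 17.4 ± 0.971 CPM. Its camera call (adjusted p = 0.0249) had an adjusted p = 0.556 with an estimated correlation, and was lost without control replicate 3 (adjusted p = 0.282) and without 10panx1 replicate 2 (adjusted p = 0.0761).

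Actin cytoskeleton, adhesion and migration genes rose, 11 of 29 with none falling, and 15 adjusted over the list alone. Myh9, the heavy chain of non-muscle myosin IIA, rose from 735 ± 68.5 to 1058 ± 102 CPM, Tpm4 from 343 ± 16.99 to 419 ± 18.8 CPM and Tln1, which links integrins to actin, from 564 ± 23.3 to 673 ± 33.7 CPM. The camera adjusted p was 8.77e-08, and the list had an adjusted p = 0.161 with an estimated correlation. Src family kinases and their regulators rose, 10 of 27 against 1 that fell, with the same counts adjusted over the list alone. Besides Src, Cblb, a ubiquitin ligase that limits tyrosine kinase signalling, rose from 73.9 ± 4.07 to 93.8 ± 2.36 CPM and Ptprc, the CD45 phosphatase, from 133 ± 5.73 to 163 ± 8.55 CPM. The camera adjusted p was 0.000874, and the list had an adjusted p = 0.18 with an estimated correlation.

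Hypoxia-inducible factor (HIF) targets went both ways, 10 of 27 rising and 3 falling, and 12 and 4 adjusted over the list alone. Ndrg1 rose from 582 ± 17.99 to 732 ± 54.03 CPM and Ero1a, an oxidase of the endoplasmic reticulum, rose by 0.24 on the log2 scale, while Higd1a fell from 266 ± 4.08 to 221 ± 11.9 CPM. By camera its adjusted p was 0.00116, with an adjusted p = 0.161 with an estimated correlation. Glycolysis genes rose, 3 of 19 with none falling, and 5 adjusted over the list alone. Slc2a3, a glucose transporter, rose from 547 ± 27.3 to 720 ± 51.9 CPM, and Hk1 and Pfkp rose by 0.26 and 0.20 on the log2 scale. Camera gave an adjusted p of 0.00102, and the list had an adjusted p = 0.477 with an estimated correlation.

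Of 36 genes of G1/S and DNA replication 7 fell and none rose, the same adjusted over the list alone. Ccne1, which encodes cyclin E1, fell from 74.9 ± 2.62 to 58.4 ± 8.52 CPM, and Cdc6 and Dtl had log2 fold changes of -0.40 and -0.29. The camera adjusted p was 6.06e-06, and the list had an adjusted p = 0.477 with an estimated correlation. Of 36 genes of G2/M and mitosis only Prc1 fell, from 64.8 ± 5.0 to 54.1 ± 3.89 CPM, and none was called adjusted over the list alone. Called genes were thus a smaller share of this list than of all tested genes. Mad2l1 and Pbk had log2 fold changes of -0.20 and -0.16 without passing (edgeR, adjusted p = 0.0507 and 0.0565). Camera gave the list an adjusted p of 0.00471, and it had an adjusted p = 0.607 with an estimated correlation, and lost the call without 10panx1 replicate 2 (adjusted p = 0.165).

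Of 34 cytosolic ribosomal protein genes 6 fell and none rose, and 7 fell adjusted over the list alone. Rps27 fell from 239 ± 17.3 to 181 ± 15.5 CPM and Rpl30 from 115 ± 7.26 to 90.7 ± 6.08 CPM. These genes, with Ftl1, Cox7c and Cox6c, have near-identical pseudogene copies and the handling of shared reads is not stated, so their values are uncertain. The adjusted p by camera was 1.41e-05, with an adjusted p = 0.477 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes fell, 5 of 30 with none rising, and 8 adjusted over the list alone. Cox7c fell from 106 ± 1.24 to 87.4 ± 4.84 CPM, and Cox6c and Cox7a2 had log2 fold changes of -0.26 and -0.23. The list had a camera adjusted p of 0.0178 and an adjusted p = 0.477 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.116) and after trends with transcript length and GC were removed (adjusted p = 0.207).

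Genes of the unfolded protein response of the endoplasmic reticulum fell, 8 of 23 with none rising, and 13 adjusted over the list alone. Calr, a calcium-binding chaperone, fell from 1212 ± 6.49 to 1043 ± 41.5 CPM, and Wfs1 and Manf had log2 fold changes of -0.40 and -0.26. The camera adjusted p was 8.64e-06, and the list had an adjusted p = 0.161 with an estimated correlation. Of 24 genes of NRF2 and oxidative stress 6 fell and 1 rose, and 7 and 2 adjusted over the list alone. Ftl1, the ferritin light chain, fell from 354 ± 16.1 to 269 ± 12.4 CPM and Gclc, which makes the precursor of glutathione, from 98.8 ± 4.76 to 74.6 ± 8.18 CPM, while Hmox1, heme oxygenase 1, rose from 476 ± 2.06 to 553 ± 9.3 CPM. The list had a camera adjusted p of 0.00921 and an adjusted p = 0.477 with an estimated correlation, and lost the call without 10panx1 replicate 2 (adjusted p = 0.0845).

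In total 14 of 31 tested lists passed camera at 9 h with the preset correlation and none with an estimated correlation. Splits of the libraries that mix the groups called up to 12 lists with the preset correlation. Such splits keep part of the group difference, so these calls need not be spurious. The fry test, which asks whether a list's genes move on balance one way, kept 5, namely Src family kinases, HIF targets, the unfolded protein response, alternative activation and actin cytoskeleton genes. Among lists that did not pass camera, immediate early and MAPK feedback genes had 8 of 27 rising and 4 falling (adjusted p = 0.2), with Dusp6 higher by 0.38 and Fos at a log2 fold change of -0.50. Microglial homeostatic genes had 2 rising and 2 falling of 12 (adjusted p = 0.784), and Csf1r and Cx3cr1 were named by the rule, rising by 0.20 and 0.31 on the log2 scale. Markers of astrocytes, neurons, oligodendrocytes, fibroblasts and lymphoid or erythroid cells had too few tested genes for a test.

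**Figure D2:**
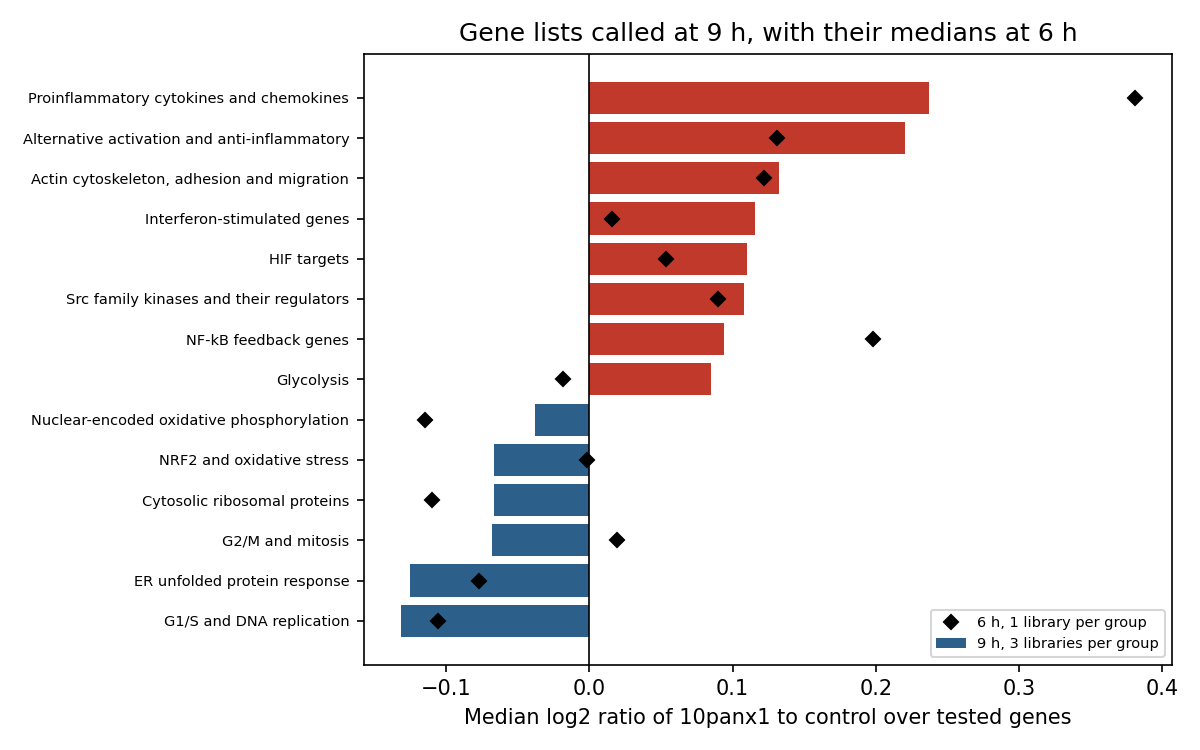
Median log2 ratio of 10panx1 to control over the tested genes of each of the 14 gene lists called at 9 h (bars, 3 libraries per group) with the medians at 6 h (diamonds, 1 library per group and no test). Red bars are higher and blue bars lower with 10panx1, and the medians of the glycolysis list (0.09 at 9 h, -0.02 at 6 h) and the G2/M list (-0.07 at 9 h, 0.02 at 6 h) differ in sign between times.

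At 6 h each group held 1 library, so the difference between them has no replicate check. Il1b lay at 58.1 CPM in the control and 102.7 CPM in the 10panx1 library, Il1rn at 352 and 521 CPM, and Src at 19.8 and 23.4 CPM. Ftl1 lay at 344 and 222 CPM and Irf1 at 11.3 and 8.09 CPM, while Arc had a log2 ratio of 0.41, opposite to its change at 9 h. Of the 1233 genes called at 9 h, 1048 (85.0%) had the same sign at 6 h, against 59.8% of 12159 genes that were not called. Among 10000 random lists matched on expression, the medians of the cytokine and NF-kB lists lay at percentile 100 and that of actin cytoskeleton genes at 99.9, while those of G1/S, ribosomal protein and oxidative phosphorylation genes lay at percentile 0 and that of the unfolded protein response at 0.12. Alternative activation and Src family genes lay at 96.85 and 96.83. Other lists called at 9 h lay nearer the middle, HIF targets at 82.2, interferon-stimulated genes at 77.04 and G2/M genes at 44.58. NRF2 genes lay at 20.65 and glycolysis genes at 8.33. Some lists not called at 9 h lay as far out, such as immediate early and MAPK feedback genes at 99.2 and p53 targets at 1.505. An extreme percentile at 6 h thus does not by itself mark out the called lists. The random lists also lack the correlation between genes of a real list. A percentile near 0 or 100 can thus arise from variation between 2 single libraries. A test of whether the 10panx1 difference itself differed between 6 h and 9 h called 0 of 15331 genes with edgeR, with 874 genes at an unadjusted p under 0.05 where chance would give 767, and DESeq2 also called 0. Without a filter on low counts edgeR called 34 genes, 28 of them with a mean of at least 50 counts and 23 with a negative estimate (9 h minus 6 h). Named here after their values were seen, these included Rbp4, with the lowest adjusted p (3.83e-25), the chemokines Ccl3 (log2 estimate -1.03, adjusted p = 7.63e-24), Cxcl2 (-0.53, adjusted p = 6.69e-05), Ccl7 (-0.60, adjusted p = 0.000435) and Ccl4 (-0.41, adjusted p = 0.0211), and Arc (-1.51, adjusted p = 0.00498). With the filter the estimates for Ccl3 and Arc were -1.03 and -1.51 and neither passed (edgeR, adjusted p = 0.777 for both). Ccl3 had log2 ratios of 0.75 at 6 h and -0.28 at 9 h, where it was not called. The calls made without a filter appeared only in fits that held control replicate 3 at 9 h, the library that stood apart. Rbp4, F2, Pzp and Slc38a3 are among the transcripts raised in it alone, and without it and without a filter 0 genes were called, against 28 to 66 without any other library at 9 h. Why genes not raised in it alone, such as Ccl3, also lost the call was not tested. Without 10panx1 replicate 2 at 9 h the filtered test called 1 gene, Entpd4b, also named after its value was seen.

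The second comparison set the 6 libraries at 9 h against the 2 at 6 h with treatment as a covariate. Levels given for it are means over both treatments, so the SDs at 9 h (n = 6) include the treatment difference. Time and any batch cannot be told apart, since the labels give no batch. Library measures also differed with time. Mitochondrial transcripts took 1.428% and 1.515% of the counts at 6 h and from 1.141% to 1.284% at 9 h. Genes with any count numbered 19550 and 19131 at 6 h and from 20305 to 21085 at 9 h. Immediate early and MAPK feedback genes rose, 23 of 27 against 2 that fell, with the same counts adjusted over the list alone. Dusp5, a phosphatase of ERK, rose from 125 to 548 ± 29.2 CPM (SD, n = 6) and Spry2 from 30.7 to 160 ± 12.3 CPM. Its camera adjusted p was 3.28e-21, with an adjusted p = 0.0563 with an estimated correlation. Of 23 cytokines and chemokines 20 rose and 2 fell, and 21 and 2 adjusted over the list alone. Lif rose from 19.6 to 176 ± 17.7 CPM and Ptgs2, the inducible cyclooxygenase, from 749 to 2560 ± 335 CPM. The list had a camera adjusted p of 8.73e-11 and an adjusted p = 0.248 with an estimated correlation. Each of 34 ribosomal protein genes rose, also adjusted over the list alone, with Rpl3 going from 910 to 1327 ± 35.1 CPM (camera adjusted p = 2.94e-08, and adjusted p = 0.255 with an estimated correlation).

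Src was higher at 9 h, from 21.6 to 74.1 ± 14.9 CPM, and 16 of 27 Src family kinases and regulators rose against 2 that fell, with the same counts adjusted over the list alone. Nedd9 rose from 42.1 to 150 ± 6.0 CPM and Cblb from 27.5 to 85.2 ± 11.5 CPM. That list had a camera adjusted p of 0.00045 and an adjusted p = 0.104 with an estimated correlation. Panx1 was lower at 9 h, with a log2 fold change of -0.39 (standard error 0.085, edgeR adjusted p = 0.000742), a call lost without the control library at 6 h (adjusted p = 0.056) and in the 10panx1 libraries alone (adjusted p = 0.0541). NF-kB feedback genes rose, 14 of 20 against 3 (camera adjusted p = 0.000248, and adjusted p = 0.303 with an estimated correlation), with Traf1 going from 39.4 to 107 ± 9.71 CPM and Nfkbiz from 202 to 412 ± 31.3 CPM. HIF targets rose, 16 of 27 against 4 (camera adjusted p = 0.000672, and adjusted p = 0.104 with an estimated correlation). Among them Pfkfb3 went from 39.0 to 168 ± 4.98 CPM, while Hmox1 fell from 893 to 523 ± 43.4 CPM. Glycolysis genes rose, 12 of 19 against 2 (camera adjusted p = 0.000717, and adjusted p = 0.577 with an estimated correlation), with Slc2a3 going from 176 to 644 ± 103 CPM. These 3 counts were the same adjusted over the list alone.

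Genes of NRF2 and oxidative stress fell with time, 14 of 24 against 3 that rose, also adjusted over the list alone, with Hmox1 going from 893 to 523 ± 43.4 CPM and Txnrd1 from 809 to 468 ± 41.8 CPM. The list had a camera adjusted p of 0.000248 and an adjusted p = 0.255 with an estimated correlation. Mitochondrially encoded genes fell, 6 of 10 against 2, with mt-Nd1 going from 2023 to 746 ± 89.2 CPM (camera adjusted p = 0.0384, and adjusted p = 0.614 with an estimated correlation). Of 21 p53 targets and apoptosis genes 9 rose and 7 fell (camera adjusted p = 0.04, and adjusted p = 0.255 with an estimated correlation), with Plk2 going from 401 to 1301 ± 90.6 CPM and Bcl2l11 from 194 to 524 ± 19.2 CPM. The counts of both lists were the same adjusted over the list alone.

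Of single genes, Il17f was at 0 counts in both libraries at 6 h and at 4.58 ± 0.717 CPM at 9 h, at least 31.5-fold higher against a floor of 3 counts per library. Tmem132b and Npc1l1 were at least 28.9-fold and 23.4-fold higher by the same floor. Fhdc1 had 2 and 1 counts at 6 h and from 193 to 269 at 9 h, a ratio of 146 with a 95% counting interval from 49.99 to 711. Hpx, the plasma heme-binding protein, was also named by the rule, with 2971 counts in the third control library at 9 h, from 3 to 10 in the other 5 and 0 at 6 h. The falls named by the rule were those of Jrk, from 8.44 to 0.829 ± 0.167 CPM, Bbs12, from 12.7 to 1.74 ± 0.219 CPM, Tmem102, Ankle1 and Rgs11. In all, 9037 of 14315 genes were called, 4528 higher and 4509 lower at 9 h, by edgeR's quasi-likelihood test in the additive model, and 10 of 31 lists passed camera. The 2 libraries at 6 h were taken to vary like those at 9 h, and intervals and floors cover counting error only.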

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

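The test of processed pseudogenes, that of a later position in the time course and the removal of trends with length and GC were chosen only after results were seen. The glycolysis list was singled out because its mean log2 CPM did not overlap between groups at 9 h, higher in each 10panx1 library, while the single 10panx1 library at 6 h lay lower than its control, by a difference of -0.00158. The difference between times was not tested for the list.

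The rise of Src and the opposite directions of the 14 lists at 9 h were weighed against technical causes. Longer transcripts tended to be higher with 10panx1, with median log2 fold changes of -0.06 over the 2644 shortest and 0.04 over the 2643 longest genes. With each library's trend on length and GC removed, Src kept a log2 fold change of 0.471 (edgeR, adjusted p = 0.00204). The medians above are small beside that value, so the removal could hardly have ended the rise of Src. Of the 14 lists 13 kept direction and call at the preset correlation, a call that none kept with an estimated correlation. The small trend and the kept values argue against that trend as the whole cause. Src stayed called in all 6 fits that left out 1 library, with adjusted p up to 0.022, though on TPM its adjusted p was 0.0505 to 0.0515. An effect of 10panx1 stays open as a hypothesis, since an unlabelled batch that follows the groups was not testable.

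Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 1233 genes and the highest of the others 0, so 1 of 10 splits gave as many genes. It called 14 gene lists and the highest of the others 12, so 1 of 10 gave as many lists. Each other split, though it called 0 genes, called from 1 to 12 lists. List calls by camera at the preset correlation thus also arose in splits that mix the groups. Each such split was still unbalanced between control and 10panx1, so part of the group difference remained in it. The rest of that difference widened the spread within each side. The splits thus cannot tell spurious list calls from a diluted group difference, and no conclusion is drawn from them. Estimated correlations of the lists called at 9 h ran from -0.0176 (HIF targets) to 0.441 (G2/M), against the preset 0.01.

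The transcripts raised in the third control library at 9 h may come from foreign RNA or reads, and the tests left the origin open. Of 12 hepatocyte markers 7 had more counts there than in the other 5 libraries at 9 h together. This was short of the 8 set in advance of the tally for liver RNA and above the bound set against it. The 7 include Hpx, which prompted the tally, and Ttr and Ahsg, with only 3 counts each there and 0 in every other library. Hpx had 2971 counts, Fgb 561 and Alb 82, but Apoa1 only 2, and Trf, with 1710 to 2593 counts, was present in all 8 libraries. Of 10 fibroblast markers 3 passed, Col1a1, Col1a2 and Col3a1, between the bounds set in advance, and processed pseudogenes took a share 2.31 SDs above the mean of the other 5, short of the 3 SDs set for reads of another organism. Of the other lists, epithelium had 2 of 8 markers raised, neuron 1 of 10, and skeletal muscle, kidney, lung and testis 0, and no biological explanation was tested.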

How the results depend on the processing

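The removal of trends with length and GC and the interaction fits with no filter and 1 library left out were added after the data were seen, and all other alternatives were planned. The 1233 genes called at 9 h became 368 and 371 with limma on log2(TPM + 1) and log2(TPM + 0.1), 45 with a log2 fold change of at least 1 and 188 with at least 1.5-fold, and from 598 to 1433 with 1 library left out, where fewer samples were tested (841 without control replicate 3). The cause of the lower counts on TPM was not tested. No called gene changed sign in any of these fits. Whether the replicate numbers pair the libraries stays open. Correlations of deviations were 0.0943, -0.00705 and 0.0741, and replicates 1 and 3 correlated best with their own number while replicate 2 did not. The fit with the replicate block called 1771 genes, 1231 of them among the 1233. The 14 lists called at 9 h became 0 with an estimated correlation and 5 with fry, and from 10 to 15 with 1 library left out. The 10 lists called for 9 h against 6 h became 0 with an estimated correlation. The interaction count of 0 became 34 with no filter and from 0 to 1 with 1 library left out. With no filter it was 32, 28 and 0 without control replicates 1 to 3. Without 10panx1 replicates 1 to 3 and with no filter it was 66, 32 and 33. The 34 calls thus appeared only with control replicate 3 in the fit, and the cause was not tested.

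Of 64 called named genes at 9 h, 34 kept the call in each alternative and 42 in each fit without 1 library, and 26 lost it on TPM. For time 29 of 31 kept it, Hpx and Panx1 being the exceptions. Of results without a call, the Panx1 estimate at 9 h ranged from -0.092 to 0.0729 with 1 library left out. Calls were gained by disease-associated microglia (lower, adjusted p = 0.0229 with no filter and 0.0228 without 10panx1 replicate 3) and by nuclear-retained RNAs (higher, 0.0295 without control replicate 3). List directions turned, with none called, for LXR targets (adjusted p = 0.67 by ranks, 0.693 to 0.991 with 1 library left out), mitochondrially encoded genes (0.568 by ranks, 0.138 to 0.931), amino acid response (0.501 to 0.853), p53 targets (0.539 to 0.823), homeostatic microglia (0.466 to 0.974), antigen presentation (0.336 to 0.984) and endothelial markers (0.224 to 0.934), and the cause was not tested. What depth limits was not separated from replicate number or the spread between libraries.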

Other observations

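Among lists outside the called ones at 9 h, heat shock genes had 3 of 16 falling and none rising (camera adjusted p = 0.187), among them Hspe1, from 157 ± 6.73 to 134 ± 10.1 CPM, and Bag3, from 44.7 ± 3.15 to 36.9 ± 2.45 CPM. Of 21 p53 targets and apoptosis genes 2 rose and 4 fell (adjusted p = 0.721), with Bcl2l1, an inhibitor of apoptosis, higher by 0.35 on the log2 scale and Gadd45a at -0.44. Of 30 genes of ATF4 and the amino acid response 1 rose and 2 fell (adjusted p = 0.831), with Atf5 at -0.33 and Slc7a5 at -0.23. Of 30 Myc targets and ribosome biogenesis genes 1 rose and 2 fell (adjusted p = 0.371), with Odc1 higher by 0.27 and Nop16 at -0.23.

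The remaining camera adjusted p-values at 9 h were 0.582 for pannexins and purinergic receptors, 0.233 for inflammasome, 0.256 for cholesterol synthesis, 0.871 for LXR targets, 0.105 for disease-associated microglia (0.0229 with no filter, 0.0228 without 10panx1 replicate 3), 0.679 for antigen presentation, 0.2 for lysosome and autophagy, 0.831 for mitochondrially encoded genes, 0.2 for histones, 0.256 for nuclear-retained noncoding RNAs (0.0295 without control replicate 3, the library with transcripts of plasma proteins) and 0.323 for endothelial markers. For LXR targets, mitochondrially encoded genes and antigen presentation the list's median and test differed in sign. The highest members of the untested marker lists were Aldoc at 121 CPM, Mbp at 5.71, Col1a1 at 4.0 (553 counts in control replicate 3 at 9 h and at most 22 in any other library), Tubb3 at 0.995 and Cd79a at 0.139 CPM.

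Both comparisons called 7 lists, 6 in the same direction, and ribosomal proteins in opposite directions (lower with 10panx1, higher at 9 h). A hypothesis that 10panx1 libraries lie further along the time course was tested across 14315 genes with disjoint control libraries. Pearson's r across genes, which are not independent replicates, was -0.151 at the lowest and -0.000624 at the highest of 3 splits. Over 10701 genes with a mean of at least 50 counts it ran from -0.14 to 0.0706. There its sign changed with the control library used for time. What would count for or against the hypothesis was written after the values were seen. No split gave a clear positive r, while a small common shift stays open. The tests on single lists leave open that some genes are further along.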
